A study of Mus musculus with 3 samples.

How the data were processed

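RNA was profiled on 3 Agilent mouse arrays of 2 colours, each set against untreated RNA from the same kind of culture. The spot intensity values were made by the authors with Agilent Feature Extraction 10.5.1.1, per the file headers, as mean signals and median local backgrounds per channel with no normalization. Also deposited is a log10 ratio of Cy5 over Cy3, which per the file headers follows background subtraction with spatial and multiplicative detrending and a linear and LOWESS dye normalization within the array. All arrays were on 1 slide and shared 1 scan, so slide and scan date set no batches apart. Per the labels, stromal cells were depleted from the T cells by a short adherence step before RNA was taken.

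From the mean and background signals, values were computed with limma 3.58.1 in R 4.3.3. The background was corrected with normexp and an offset of 50, and each array was normalized by loess with a span of 0.3, with control spots and spots with outlier flags at weight 0. Median centring, used as an alternative on all probes or on measured genes, took the place of loess and subtracted a constant from each array. Each array had 43379 spots that were not controls, for 41174 probes, 245 of them spotted 10 times. Spots of a probe were averaged. Probes were named through RefSeq accessions where the reference table (assembly GRCm38, used for names only) held them, which named 25097 probes. Another 6333 were named by symbol and 1640 by synonym, and 8104 kept the name in the file. A gene was represented by its probe of highest mean brightness, giving 27729 genes. Positions are those of the probes on mm9, per the file headers. From 117 to 130 spots per array carried an outlier flag and 0 were saturated.

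A gene counted as measured where at least a share of 0.5 of its spots were well above background, in both channels for calls and in at least 1 for list medians. With 1 array per comparison no test was possible, and a rule of size of 2-fold was used. Each of the 27 gene lists was described by its median and by the number of 10000 random lists, matched on brightness in 20 bins, whose median lay below it. Channels were compared across arrays after Aquantile scaling. For a gene above background in 1 channel only, a lower bound was computed against the higher of its own dim signal and the lowest signal above background in that channel. The own signal was the higher in the bounds given here. These bounds are open to dye bias. Oas2 was at least 2.13-fold higher in treated stromal cells, and Bpifb4 at least 2.84-fold and Vat1l at least 2.59-fold lower in treated T cells at 72 h, where Sgip1 was at least 2.01-fold higher.

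The genes named were the 12 highest and 12 lowest of each array, 8 of each direction for a difference between arrays, up to 4 members of a list past 2-fold and a set of genes listed beforehand. Clone names and near-identical families were counted but not named unless they belonged to a list. Of these, the text gives those that illustrate each group, and single values of some genes are not reported here. Lists, rule and alternatives were fixed before the data were examined, and the closing part says which were added later.

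The steps were checked on simulated arrays with 200 changed spots. With the offset of 50, simulated 4-fold changes returned median log2 values of 1.80, 1.77 and 1.69 on the stromal, 24 h and 72 h arrays, and simulated 2-fold changes passed the rule in 14%, 16% and 24% of spots. With an offset of 0 the 4-fold changes returned 2.02, 2.02 and 2.03. The offset thus shrinks the ratios of dim genes and lowers the counts of called genes. On each real array the counts with an offset of 0 were higher, but still below those with the Agilent log ratio. No unchanged spot passed the rule. The simulated noise was smaller than the SD between real probes of a gene and held no gene-specific dye effect, so this does not show that real calls are free of false ones. The list percentile was checked on 16282 simulated genes of the 72 h array, where 100 of 100 lists of 20 genes shifted by 0.5 lay above the central range. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used for lists and counts.

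Among 138 genes above a mean log2 brightness of 16 on the stromal array the median ratio after loess was 0.52, against 0.18 with the Agilent log ratio. It was 0.58 against 0.21 for 93 genes in T cells at 24 h, and 0.31 against 0.08 for 94 genes at 72 h. Values of very bright genes thus carry a positive shift of that order beside the other genes.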

Results

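Gene expression was measured in mouse T lineage cells and in the stromal cells that support them, each with and without phospho-ascorbate (pAsc), a form of vitamin C. The T lineage cells were grown from bone marrow progenitors of C57BL/6 mice on OP9-DL1 cells, a bone marrow stromal line that presents the Notch ligand Dll1, with the cytokines Flt3L and IL7. pAsc was present at 800 µM for the last 24 h of a 14-day culture, for 72 h of a 17-day culture, or for 24 h on the stromal cells alone. Each of the 3 comparisons was made on 1 array, with untreated RNA in Cy3 and treated RNA in Cy5. There was no replicate array and no dye swap, so no p-value is given. A gene-specific dye effect cannot be separated from treatment on a single array. Genes were called by size, as at least 2-fold apart among genes well above background in both channels. Those numbered 14346 on the stromal array, 16971 in T cells at 24 h and 16282 in T cells at 72 h.

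Technical spread was small beside the 2-fold rule. Repeat spots of 1 probe had a log2 SD of 0.069 on the stromal array, 0.071 in T cells at 24 h and 0.068 at 72 h. Different probes of 1 gene had an SD of 0.17, 0.14 and 0.17, pooled over genes with several measured probes. Some called genes differed more between their probes, as given for them below. The added spike-in RNAs gave slopes of observed on nominal log ratio of 0.950, 0.927 and 0.922, in the same order. The number of arrays limits the precision, since these spreads hold no variation between cultures.

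The first comparison asked what 72 h of pAsc does to developing T cells, where the study's title names positive selection. Both chains of the coreceptor CD8 were higher in treated cells. Cd8b1 was 3.08-fold higher (log2 ratio 1.62) and Cd8a 2.47-fold higher (log2 ratio 1.31). Zap70, the kinase that carries the T cell receptor signal, was 2.45-fold higher, and Slamf6, a receptor of the SLAM family, was 2.60-fold higher in its brightest probe, with its 2 probes at log2 ratios of 0.78 and 1.38. On the mm9 build the Cd8b1 probe lies on chromosome 6 at 71287068 to 71287126, the Cd8a probe on chromosome 6 at 71327330 to 71327389 and the Zap70 probe on chromosome 1 at 36838210 to 36838269. All 3 measured probes of Cd8a gave log2 ratios from 1.31 to 1.53. Cd4 had a log2 ratio of -0.07, Cd3e of -0.04 and Lck of -0.27. Cd4 was near the floor, at a mean log2 brightness of 6.49 against 6.47 on the stromal array. Its ratio thus does not show whether it changed.

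Among genes of earlier and of other blood lineages, some were at least 2-fold lower in treated cells at 72 h and 0 listed ones were at least 2-fold higher. Lyl1, a transcription factor of early progenitors, was 5.87-fold lower and the progenitor surface marker Cd34 was 3.46-fold lower. Cpa3, a mast cell protease, was 4.37-fold lower, and Ctsg, a protease of myeloid granules, was 4.19-fold lower, at a log2 ratio of -2.07 against -3.34 with the Agilent log ratio. Of 14 measured B cell genes, with a median of -0.22, or -0.69 when centred on measured genes, 5 were at least 2-fold lower and 0 at least 2-fold higher, with Vpreb1 at a log2 ratio of -1.57, Blk at -1.11 and Blnk at -1.02. Of 22 genes of NK, gamma-delta and cytotoxic cells, 4 were at least 2-fold lower and 0 higher, among them Gzma at -1.61 and Sox13 at -1.34. Their median of -0.32 was below all 10000 random lists. With median centring on all probes it was 0.085, where all measured genes had a median of 0.54, so it stayed below other genes. Centring on measured genes did not turn its sign. Other lowest values were those of the complement gene C3 at -1.94, where its other probe was at -0.44, Lmo1 at -1.66, Nfe2 at -1.54 and Muc13 at -1.58. Of 18 measured genes of T lineage commitment 2 were at least 2-fold lower and 0 higher, with a median of -0.09 inside the central 95% of random lists. They were Il2ra at -1.09 and Myb at -1.29, with its 4 probes from -1.29 to -0.44. The lists of progenitor, myeloid and mast cell genes had 3 of 13, 2 of 13 and 1 of 7 measured members at least 2-fold lower. Their medians of -0.01, 0.004 and -0.04 lay inside that range.

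**Figure D1:**
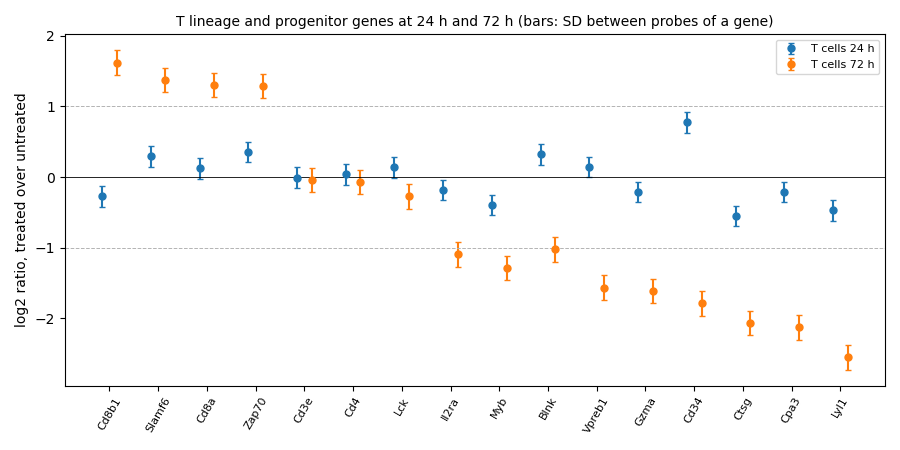
Log2 ratios of treated over untreated T cells for named genes at 24 h and at 72 h, with dashed lines at 2-fold. Bars are 1 SD between different probes of a gene, pooled over the genes of that array with several measured probes. The bar is the same for every gene of an array, 0.14 at 24 h and 0.17 at 72 h, also where a gene has 1 probe. It is not the spread of the gene shown. Cd8b1 lies at 1.62 at 72 h and -0.27 at 24 h, and Lyl1 at -2.55 and -0.47.

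In all, 37 genes were at least 2-fold higher and 62 at least 2-fold lower in T cells at 72 h, against 116 and 166 with the Agilent log ratio and 1558 and 12 with median centring on all probes. Genes of stromal and connective tissue were among the higher ones. The 30 measured stromal genes had a median of 0.50, or 0.265 with the median over probes, and 4 of them were at least 2-fold higher. Collagen chains had a median of 0.48, and both medians lay above all 10000 random lists. Of the 37 higher genes, 15 were at least 2-fold brighter in untreated stromal cells than in untreated T cells, against 14.0% of all measured genes. Without such genes the count was 22, an alternative chosen after the data were seen. Within the list of coreceptor and positive selection genes, 3 of 27 measured members were at least 2-fold higher and 1 was lower. Its median of -0.07 lay inside the central 95% of random lists matched on brightness. The list of T cell receptor complex and signalling genes had a median of -0.15, below the central 95%, with 18 of 23 members below 0, 1 at least 2-fold higher and 0 lower. Receptor rearrangement genes also had a median of -0.15, below that range, with 0 of 21 past 2-fold. Median centring on all probes gave these lists medians of 0.56 and 0.46, where all measured genes had a median of 0.54. Centring on measured genes gave 0.01 and -0.08. Neither centring removes a dye effect that depends on brightness. The median of all measured genes was 0 when centred on them and 0.005 after loess. The sign of the T cell receptor list thus depends on the loess step, while that of the rearrangement list turned only with the shift of all genes. More stromal RNA in the treated sample would also lower genes absent from stromal cells, and random lists were matched on brightness only. Lgals7 and Myo6 had the highest ratios among genes named here, with log2 values of 2.32 and 2.03. The value of Lgals7, a dim gene, was 4.33 with the Agilent log ratio. The 3 measured probes of Myo6 ranged from -0.17 to 2.03, so its value rests on the brightest. S100a4 and Aldoa were above a mean log2 brightness of 16, where loess left a positive median, and Ldha was at 15.8. The other probe of Ldha was at 0.22. With the Agilent log ratio the values of these 3 genes of 1.37, 1.12 and 1.14 became 1.07, 0.81 and 0.86.

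After 24 h the T cell array was led by genes of stromal and connective tissue. All 29 measured stromal genes had log2 ratios above 0, with a median of 0.69, above all 10000 random lists. Of these, 6 were at least 2-fold higher, among them Fbn1, encoding fibrillin, at 1.27 in its brightest probe and 0.765 in the other, and Postn at 1.14. Collagen chains had a median of 0.63, with 5 of 22 at least 2-fold higher. Single genes outside these lists were also at least 2-fold higher, among them Hspb1 at 1.38 and Gdf15 at 1.22. Atf3 at 1.20 was the 1 of 23 unfolded protein and amino acid stress genes past 2-fold, in a list whose median of 0.03 lay inside the central 95% of random lists. Hmox1 at 1.13 was the 1 of 27 oxidative stress genes past 2-fold, in a list whose median of 0.14 lay above that range. Among genes that could be named, Il1rn had the highest ratio at 2.97-fold. On the stromal array Il1rn, Hspb1 and Hmox1 had a mean log2 brightness of 13.62, 13.55 and 13.11, against 9.85, 9.94 and 10.94 here. Gdf15 was at 11.81 there and 10.59 here, and Atf3 at 6.79 and 10.43. More stromal RNA in the treated sample, which is left open below, may thus also raise those brighter on the stromal array. In all, 53 genes were at least 2-fold higher and 2 lower, against 147 and 32 with the Agilent log ratio and 748 and 2 with median centring on all probes. The 2 were Csf2, encoding the cytokine GM-CSF, at -1.55 (-2.25 with the Agilent log ratio) and Bpifb4 at -1.54. Of the 53 higher genes, 35 were at least 2-fold brighter in untreated stromal cells than in untreated T cells, against 20.2% of all measured genes. Without such genes the count was 18, an alternative chosen after the data were seen.

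Of the genes in the T lineage lists, 1 passed 2-fold at 24 h, the early response gene Egr1, which was 2.15-fold higher. The 28 measured coreceptor and positive selection genes had a median of -0.13, below all 10000 random lists, but at 0.44 with median centring on all probes and 0.025 when centred on measured genes. The lists of T cell receptor signalling, rearrangement and T lineage commitment had medians of -0.04, -0.015 and -0.03, inside the central 95%. The log2 ratio was 0.12 for Cd8a, -0.27 for Cd8b1, 0.35 for Zap70 and 0.04 for Cd4. Cd8a and Cd4 were dim here, at a mean log2 brightness of 6.87 and 6.60, where the offset shrinks ratios. Rag1 was at -0.11, Tcf7 at 0.08, Cd5 at -0.23, Cd69 at -0.32 and Il7r at -0.68. The 22 measured NK, gamma-delta and cytotoxic genes had a median of -0.27, below all 10000 random lists, and 0 of them were at least 2-fold apart in either direction. With median centring on all probes their median was 0.11, where all measured genes had a median of 0.41, so it stayed below other genes. Centring on measured genes did not turn its sign.

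**Figure D2:**
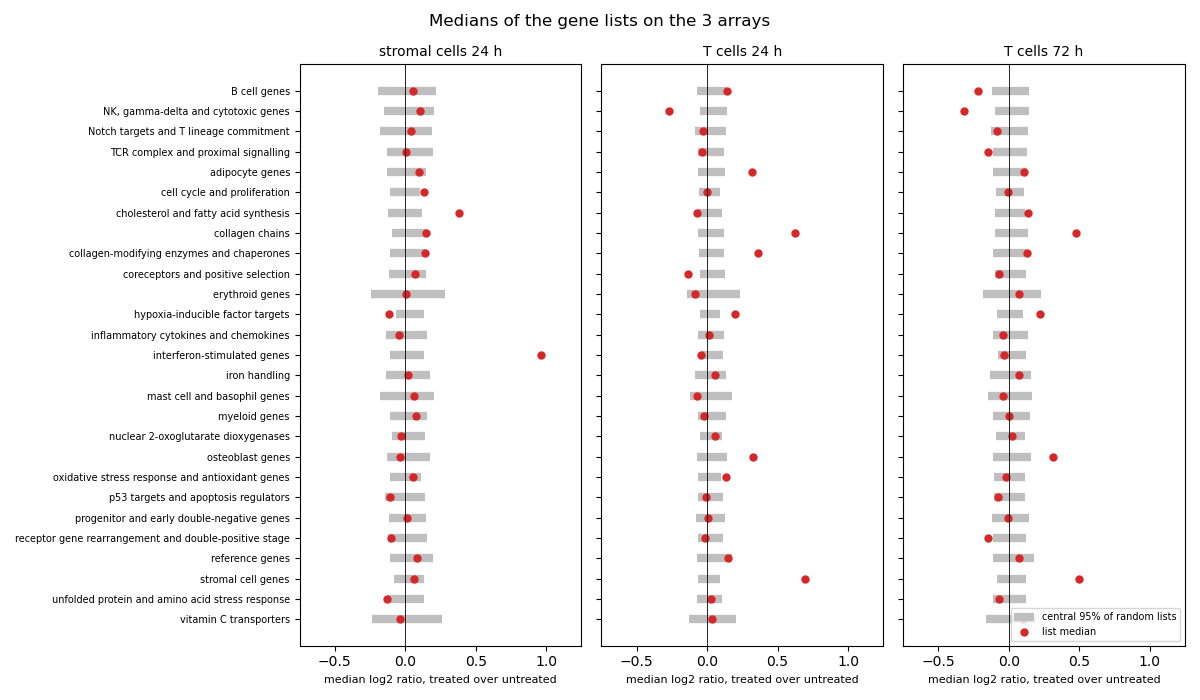
Median log2 ratio of treated over untreated for each of 27 gene lists on each array (points), with the central 95% of medians of random lists of the same size matched on brightness (grey bars). Interferon-stimulated genes stand at 0.96 on the stromal array and stromal genes at 0.69 in T cells at 24 h.

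The change between 24 h and 72 h was read from the difference of the T cell arrays, in which a constant dye effect of a probe cancels. The log2 ratios differed by at least 1 in 87 of 15741 genes, 30 higher at 72 h and 57 lower, against 278 with the Agilent log ratio, 271 with plain background subtraction and 183 with an offset of 0. Among genes that could be named, Cd8b1 had the largest positive difference at 1.90, and Cd34 the largest negative at -2.56. Lyl1 differed by -2.08 and Cpa3 by -1.92. At both times 4 genes were at least 2-fold higher, namely Arc, Col1a2, Fbn1 and Mgp, where independent lists would share 0.107. That count depended on the setting, with 14 for the Agilent log ratio, 2 for the median over probes, 505 for median centring on all probes and, in alternatives chosen after the data were seen, 1 after a running median over brightness was subtracted and 0 without genes brighter in stromal cells. With the Agilent log ratio Col1a2 was at 0.93 at 24 h and 0.83 at 72 h, and its other probe at 72 h was at 0.17. Of genes above background in both channels at both times, 0 were at least 2-fold lower at both. Bpifb4, above background only in untreated cells at 72 h, was at -1.54 at 24 h and at least 2.84-fold lower at 72 h. The stromal array, a different culture, shared 4 higher genes with T cells at 24 h and 7 with T cells at 72 h, where independent lists would share 0.211 and 0.12. Among lower genes it shared 1 with T cells at 72 h, Trib3, where independent lists would share 0.027. Col1a2 and Mgp are among both the 4 and the 7 higher genes. A fixed dye effect of a probe is common to all arrays and could add to each shared count. The shared counts thus do not by themselves show a shared response.

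Stromal cells treated alone for 24 h had higher levels of interferon-stimulated genes. Of 28 measured members, 14 were at least 2-fold higher and 0 lower, with a median log2 ratio of 0.96, above all 10000 random lists. Oasl2 was 4.93-fold higher and Ifit1 4.06-fold higher, both products of the antiviral response. Oas1a was at a log2 ratio of 1.95, Usp18 at 1.92, Irf7 at 1.53 and Isg15 at 1.41. The Oasl2 probe lies on chromosome 5 at 115362168 to 115362227. The same list had medians of -0.04 (SD 0.22 between members) and -0.03 (SD 0.43) in T cells at 24 h and 72 h, with 0 members past 2-fold at either time. At 72 h Ifit1 was at 0.98, or 1.13 with the Agilent log ratio, and Oas1a at 0.62. Ifi27l2a, an interferon-induced gene outside the list, was at 1.89 in stromal cells and 1.11 in T cells at 72 h. Outside the list, the matrix gene Mgp was at 1.65 and the class I gene H2-K1 at 1.13, with its 4 probes from 0.58 to 1.13. Genes of cholesterol and fatty acid synthesis had a median of 0.38, with Mvd at 0.95, and 0 of 26 passed 2-fold in either direction.

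Genes lower in treated stromal cells included Trib3, a pseudokinase of the stress response, 4.45-fold lower in its brightest probe (log2 ratio -2.15) and at -0.999 in the other, and Chac1, at a log2 ratio of -1.45. In T cells Trib3 was at -0.47 at 24 h and -1.22 at 72 h. Its decrease was thus not particular to stromal cells, and a dye effect of its probe is not set apart. Of 37 measured targets of hypoxia-inducible factor, 2 were at least 2-fold lower, 0 at least 2-fold higher and 12 above 0. The 2 were Ankrd37, 3.21-fold lower (log2 ratio -1.68, or -2.305 with the Agilent log ratio), and Ndrg1 at -1.25. In T cells at 24 h and 72 h Ankrd37 was at 0.17 and -0.90, and Ndrg1 at -0.22 and -0.68. The prolyl hydroxylase subunits P4ha1 and P4ha2, which modify collagen with ascorbate as a cofactor, were at -0.64 and -0.73. The list of collagen-modifying enzymes and chaperones that holds them had 16 of 22 measured members above 0 and a median of 0.142, just above the central 95% of random lists. The median of the targets of hypoxia-inducible factor was -0.12, and median centring turned it to 0.65, or 0.008 when centred on measured genes. In all, 62 genes were at least 2-fold higher and 17 lower, against 136 and 110 with the Agilent log ratio and 2835 and 2 with median centring on all probes. Col1a2 was at 1.12 in its brightest probe and at -0.31 in the other, and at 0.69 with the Agilent log ratio, so its place among the 62 rests on the brightest probe and on the setting. Col1a1 was at 0.46, Kitl at -0.79, Cxcl12 at 0.36 in its brightest probe and -0.40 in the other, Il7 at 0.11 and Dll1 at -0.22.

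The stromal response was set against the T cell response at the same time. The log2 ratios differed by at least 1 in 241 of 13741 genes, 52 higher and 189 lower on the stromal array, against 573 with the Agilent log ratio, 567 with plain background subtraction and 407 with an offset of 0. Highest were Dhx58 at 2.31, Oasl2 at 2.24 and Usp18 at 2.13. Lowest were Chac1 at -1.95, Sox9 at -1.87 and Postn at -1.87. Postn, a stromal gene, was at -0.74 on the stromal array and 1.14 in T cell RNA, where all 29 measured stromal genes were above 0. Carried-over stromal RNA, left open below, may thus enter the 189, which are not all a difference in response between cell types. Across genes, which are not independent replicates, the ratios correlated at 0.07 between these arrays and at 0.50 between the T cell arrays.

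Untreated cells of day 17 were set against those of day 14, both in Cy3. These are 1 sample each on separate arrays, so culture time is not set apart from other differences between the samples, among them the level of stromal RNA. Of 15847 genes, 1217 were at least 2-fold higher at day 17 and 580 lower. Cd8b1 was higher by a log2 value of 3.27 and Cd8a by 2.48. Cd4 differed by 0.04 but was near the floor on both arrays, so this value does not show whether it changed. B cell genes had a median of -1.23, with Blnk at -2.77. Stromal genes had a median of 1.78, and 22 of 29 were at least 2-fold higher. Their median level in untreated T cell RNA was 17.1% of that in untreated stromal cells at day 14 and 58.1% at day 17. In treated cells against treated stromal cells it was 26.0% and 64.9%. Median scaling in place of quantile scaling moved the share of genes higher at day 17 from 67.7% to 80.3%.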

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

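The tests of dye bias depending on brightness were set before their results were seen, and the tests of probe dye bias, carried-over stromal RNA, the stromal response, the share of B-lineage cells and culture time only after. The differences listed first were not tested, since each rests on 1 array per group. Plac8 had a log2 ratio of 1.35 in stromal cells and -1.42 in T cells at 72 h. B cell genes had a median of 0.14 in T cells at 24 h and -0.22 at 72 h. Genes of cholesterol and fatty acid synthesis had a median of 0.38 in stromal cells, -0.071 in T cells at 24 h and 0.137 at 72 h, with the 24 h value at 0.482 when centred on all probes and 0.071 when centred on measured genes. Targets of hypoxia-inducible factor had a median of -0.12 in stromal cells, 0.20 in T cells at 24 h and 0.22 at 72 h, with the stromal value at 0.651 and 0.008 under these centrings.

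Stromal genes were higher in treated T cell RNA at 24 h, with a median of 0.69. The response seen in stromal cells treated alone is argued against, since the same genes had a median of 0.064 (SD 0.497) on the stromal array. Stromal cells in culture with T cells were not measured by themselves, so a response of these stays open. Dye bias depending on brightness is argued against as the whole cause, since the median was 0.75 after a running median was subtracted. More stromal RNA carried over in the treated sample may account for it and stays open. Of 1402 other genes at least 4-fold brighter in stromal cells, 93.9% had ratios above 0, with a median of 0.37 (SD 0.27), but these genes were dimmer than the list and the offset shrinks dim genes, and with an offset of 0 the values of 0.43 (SD 0.32) and 0.71 lay within 1 SD, so the test does not decide. More stromal RNA in the treated sample would also lower genes absent from stromal cells. The small medians below 0 of the coreceptor, T cell receptor, rearrangement and NK lists at 24 h and 72 h are open to this, which was not tested.

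At 72 h 3 of 13 progenitor, 5 of 14 B cell, 2 of 13 myeloid and 4 of 22 NK, gamma-delta and cytotoxic genes were at least 2-fold lower and Cd8a, Cd8b1 and Zap70 higher in treated T cells. A constant dye bias of the probes is argued against as the whole cause for 20 members past 2-fold. The 20 belong to these lists and to the mast cell, coreceptor and T cell receptor lists. They had a signed median of 0.27 (SD 0.36) at 24 h and 1.30 at 72 h. They were chosen by their 72 h values, which by itself favours a larger median at 72 h. A lower share of B-lineage cells may contribute and cannot be told apart, since 14 B cell genes had a median of -0.22 (SD 0.59) and 3 of them were above 0. A treated sample further along the course of the culture is a candidate explanation for part of the pattern and stays open, since 82.1% of 78 called genes outside stromal genes (51 of 60 lower and 13 of 18 higher ones) had the same sign in untreated day 17 minus day 14, against 52.1% of all such genes. Other values go the opposite way, as the shared untreated day 17 channel also would, with NK, gamma-delta and cytotoxic genes at -0.32 with pAsc and 0.32 for day 17 minus day 14, hypoxia targets at 0.22 and -0.66, and 2 genes of a near-identical family at 1.97 and 1.91 with pAsc and -2.68 and -2.61. In untreated cells stromal genes were at 17.1% of their stromal cell level at day 14 and 58.1% at day 17. More stromal RNA at day 17 would by itself lower genes absent from stromal cells. The 52.1% is not matched for this, so the share among lower genes does not set the course of the culture apart from stromal RNA.

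Interferon-stimulated genes were higher in treated stromal cells, with a median of 0.96. Dye bias of the probes is argued against, since the median was -0.04 (SD 0.22) in T cells at 24 h with the same dyes. Some members were dim there, where the offset shrinks ratios, among them Ifit1 and Oas1a at a mean log2 brightness of 6.97 and 7.05. With the Agilent log ratio these genes were at 0.425 and 0.36 there. Oasl2, at a brightness of 9.16, had a log2 ratio of 0.06. Dye bias depending on brightness is argued against too, since the median was 0.94 after the running median. A response to pAsc and a difference between the cultures compared may both account for it, and 1 array holds no test between them.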

How the results depend on the processing

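Apart from median centring, the choice of processing moved the counts of genes past 2-fold far more than it moved directions. Median centring on all probes turned the sign of 8 list medians outside the random range, and centring on measured genes that of 5. The causes were not tested except where the construction or the simulation shows them. Centring on measured genes, the running median and the count without genes brighter in stromal cells were added after the data were seen. In what follows each count of the stromal array, of T cells at 24 h and of T cells at 72 h is given as higher and lower genes. The Agilent log ratio gave 136 and 110, 147 and 32, and 116 and 166. Plain background subtraction gave 155 and 88, 160 and 30, and 117 and 132. An offset of 0 gave 108 and 32, 113 and 7, and 85 and 104, in the direction the simulation shows for the offset. No background correction gave 27 lower genes on the stromal array. Genes that differed between the T cell arrays numbered 278, 271 and 183 with the Agilent log ratio, subtraction and offset 0, and between the stromal and T cell arrays 573, 567 and 407. Genes in the same direction at both T cell times numbered 14, 10 and 7. The median over probes gave 10 lower genes on the stromal array, 32 higher in T cells at 24 h and 24 higher at 72 h, with 150 between the stromal and T cell arrays and 2 at both T cell times. It also turned Col11a1 in T cells at 72 h from 1.14 to -0.017.

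Median centring on all probes shifted the median of the measured genes to 0.64 on the stromal array, 0.41 in T cells at 24 h and 0.54 at 72 h. It gave 2835 higher and 2 lower, 748 higher, and 1558 higher and 12 lower, with 505 at both T cell times. Both that shift and the absence of loess enter these counts. Centring on measured genes removed the shift but was also done without loess. It gave 244 and 50, 154 and 25, and 110 and 123, with 131 between the T cell arrays and 44 at both times. Centring on all probes turned the sign of list medians below 0. In T cells at 72 h these were T cell receptor signalling at 0.557, receptor rearrangement at 0.464 and cytotoxic genes at 0.085. In T cells at 24 h they were coreceptors at 0.437, cytotoxic genes at 0.109 and cholesterol synthesis at 0.482. In stromal cells they were hypoxia targets at 0.651 and the unfolded protein response at 0.798. Centred on measured genes, T cell receptor signalling was at 0.014, coreceptors at 0.025, hypoxia targets at 0.008, the unfolded protein response at 0.155 and cholesterol synthesis at 0.071. The running median left 1 gene at both T cell times. Without genes brighter in stromal cells, 18 genes were higher at 24 h, 22 at 72 h and 0 at both.

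The count for untreated day 17 against day 14 reached 2956 with plain subtraction and was within 1.5 times of 1797 otherwise. Filters on background left every count within 1.5 times. No spot was saturated, so leaving out saturated spots changed nothing. No paired analysis was possible because each comparison rests on 1 array. Signal over background limits dim genes most.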

Other observations

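Other gene groups of connective tissue lay above the random lists in T cell RNA. Genes of osteoblasts had a median log2 ratio of 0.32 in T cells at 24 h and 0.32 at 72 h, and adipocyte genes of 0.32 at 24 h and 0.11 at 72 h, the last inside the central 95% of random lists. Collagen-modifying enzymes and chaperones had medians of 0.36 and 0.13, and of 0.142 on the stromal array. Stromal genes moved with them, at medians of 0.69 and 0.50. At day 14 osteoblast genes were at 21.5% of their stromal cell level in untreated and 30.7% in treated cells, and stromal genes at 17.1% and 26.0%. Of 27 lists, 21 lay inside the central 95% of random lists on the stromal array, 16 in T cells at 24 h and 17 at 72 h. Nuclear dioxygenases that use 2-oxoglutarate, a class of enzymes for which ascorbate is a cofactor, had medians of -0.03, 0.06 and 0.02 on these arrays, and 0 of them were at least 2-fold apart. Vitamin C transporters had medians of -0.04, 0.04 and 0.10. Slc23a2 was at a log2 ratio of -0.04 in stromal cells, -0.002 in T cells at 24 h and 0.35 at 72 h.

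Across genes, the change from day 14 to day 17 in untreated cells correlated with the pAsc ratio at 72 h at 0.24, where the shared channel imposes a negative sign, and with that at 24 h at 0.45, where it imposes a positive sign. Genes brighter in stromal cells were not left out. Stromal genes were higher in all of these measures, with medians of 1.78 for day 17 minus day 14, 0.69 at 24 h and 0.50 at 72 h. The correlations thus do not set culture time apart from the level of stromal RNA.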
